A study of Zea mays with 4 samples.

How the data were processed

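Total cellular RNA was sequenced from the root tips of maize (Zea mays) seedlings of B73, the inbred line from which the maize reference genome was built. Per the labels' protocols, seeds were germinated at 28 °C under continuous light, and 3-day seedlings were kept for 2 h in gently swirled water at 28 °C before dissection. The last 1 mm of both primary and seminal roots was collected as 1 pool, so both root types share every value and cannot be told apart. RNA was extracted with TRIzol and treated with DNase. Libraries were made from 1 µg of RNA with a strand-keeping kit, adaptors with unique molecular identifiers (UMIs, random tags that mark copies of 1 molecule) and plant ribosomal RNA removal. The 4 samples are labelled as biological replicates of 1 group. Whether each came from a separate seed batch is not given in the sources used here, so every test below measures only the spread between these samples.

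The authors deposited estimated counts of reads per gene, not normalized, under NCBI gene numbers. Per the submitters' processing notes, Trimmomatic 0.36 and 0.39, STAR 2.7.10b, SAMtools, UMI-tools, deepTools and HTSeq were used, with no role or parameter named. The genome build and annotation release are not given in the sources used here. Between 5.17% and 5.64% of the nonzero values in a library were not whole within a tolerance of 0.001, and these genes held 7.31% to 8.65% of the counts. Such fractions can arise where a read is shared between genes, in which case near-identical copies are of uncertain level. How fractions were assigned, whether UMIs were collapsed and whether strand was used in counting are not given in the sources used here. The per-sample values and the joint table held the same numbers.

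Library totals were 26131723, 24246104, 26829395 and 23385589 counts for replicates 1 to 4. A count of 0 allows a level of up to 0.115, 0.124, 0.112 and 0.128 CPM (counts scaled to a library total of 1e+06) in these libraries, taken as 3 counts of the total. These limits cover counting error only. Shares and CPM were computed on the values as deposited, and values were rounded to whole numbers before count models. The planned unit was TPM, which also divides by transcript length. No exon lengths were at hand, and the fallback set before the data were examined, CPM, was used throughout. CPM does not correct for transcript length, so levels of different genes are compared as read counts.

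Of 48174 genes, 48127 matched the gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which was used for names only. That table holds no gene descriptions. The 30 gene lists written as description patterns before the data were examined therefore matched few genes: 22 patterns matched none, and 44 genes matched in all. They were replaced by 29 lists of 506 genes, chosen by gene name after the tables were at hand and before the counts of any named gene were looked at. No endodermal, root cap or root hair list could be built from names, and the planned contrast of mitosis with the endodermal barrier was not run.

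A gene was called detected at 1 CPM or more in every library. With edgeR 4.0.16 in R 4.3.3, genes were filtered with filterByExpr and scaled by TMM (factors 1.00, 1.00, 0.996 and 0.997), leaving 22752 genes. Variation beyond counting error was tested per gene with a chi-square test of the 4 counts against Poisson error. Variation beyond that of genes of equal abundance was tested with edgeR's quasi-likelihood dispersions against their trend, by an upper-tail F test. Both were adjusted by Benjamini-Hochberg at 0.05. Each list was given its share of counts, its median log2(CPM + 1), and the percentile of that median among 10000 random lists of equal size drawn from genes with a count. Members with no count stay in the median, which places lists that hold many of them low. Differences between lists were tested by a two-sided exact sign-flip permutation over libraries, for which 2 of 16 sign patterns is the smallest share that 4 libraries can give. The ratio of the highest to the second member of each list was tested with limma 3.58.1 on log2 values with a pseudocount of 0.5, adjusted over 29 lists. List membership was tested against the variable genes by Fisher's exact test.

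Named genes follow a rule set before the data were examined: the 25 genes of highest mean CPM, the 3 highest members of each list, and up to 15 genes with the smallest p among those more variable than others of their abundance. Other genes are named as chosen after their values were seen.

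The tests of spread were tried on simulated data for the 22752 genes in 4 libraries with 200 genes given extra spread. These 200 were drawn only from genes above a set total count, so the recovery does not cover genes of low count. The variability test recovered 59% of genes with a coefficient of variation of 31.6% and 92% of those with 70.7%, with 2 false calls. With equal spread it made 0 calls, and the chi-square test made 0 calls on pure Poisson counts. The limma step recovered 15 of 15 true ratios and called 1 of 14 null ratios. Those ratios were simulated directly, so this trial does not cover the picking of the highest member on the same values. Alternatives were RLE size factors, library sizes alone, no filter on low counts, a non-robust prior, DESeq2 1.42.0 dispersion outliers, other detection limits and pseudocounts, removal of the 25 most abundant genes, and each replicate left out in turn. Figures were drawn with matplotlib 3.10.9.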

Results

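The series describes the cellular transcriptome of maize root tips after 2 h in aerated water. It has 1 group, 4 biological replicates of the last 1 mm of pooled primary and seminal roots, and no second condition. The comparisons are therefore between genes, between gene groups and between replicates. Library totals were 26131723, 24246104, 26829395 and 23385589 counts.

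The 25 most abundant genes included genes of the cell wall, sucrose cleavage, glycolysis, tubulin and translation. LOC542371, named HRGP for a hydroxyproline-rich glycoprotein of the cell wall, was the most abundant at 5498 ± 418 CPM (SD, n = 4). LOC542725 (grp1) followed at 3992 ± 205 CPM, then sus1, a sucrose synthase gene, at 3769 ± 276 CPM, hsp70-4, a chaperone gene, at 3715 ± 105 CPM, and glu1, a beta-glucosidase gene that acts on benzoxazinoid glucosides, at 3184 ± 187 CPM. In replicate 1 sus1 was below hsp70-4 (3390 against 3599 CPM) and in the others above it, so their order was not resolved. Among the 25 most abundant genes were also aldolase1 (2605 ± 133 CPM) and eno1 (2041 ± 78.5 CPM), which encode glycolytic enzymes, and LOC542592 (RGP, 1986 ± 121 CPM). EF1A, a translation elongation factor gene, stood at 1613 ± 35.5 CPM. The alpha-tubulin genes tua4, TUA1 and TUA2 stood at 2217 ± 79.7, 1800 ± 84.95 and 1223 ± 30.5 CPM. TUA1 and TUA2 share a synonym in the gene table, and the split of reads between them is uncertain. LOC100384100, a long noncoding RNA gene, reached 2668 ± 223 CPM. The 25 genes together took 5.68 ± 0.133% of all counts (SD, n = 4), and the top 1669 genes were needed to reach 50% of them.

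Detected genes were mostly protein coding. Of 48174 genes, 20971 (43.5%) reached 1 CPM in every library, and 15914 had no count in any. Protein-coding genes held 19401 of the detected genes and 96.3 ± 0.0941% of counts. Long noncoding RNA genes held 640 detected genes and 1.66 ± 0.0557% of counts, small nucleolar RNA genes 0.735 ± 0.0564%, and small nuclear RNA genes 0.150 ± 0.00956%. Genes annotated as ribosomal RNA held 0.00115 ± 6.54e-05% of counts. How reads shared between genes were counted is not given, so this share does not measure how well the removal step worked.

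Nearly all measured genes of the cell division lists were detected. All 10 core and linker histone genes, all 18 DNA replication genes, all 13 mitosis and cytokinesis genes and all 8 kinesin genes reached 1 CPM in every library, as did 10 of 11 cyclin D and cell cycle regulator genes. The histone list was led by hon110 (551 ± 25.5 CPM) and hon102 (509 ± 26.9 CPM), both linker histone genes. RNRL1, for the large subunit of ribonucleotide reductase, led DNA replication at 245 ± 10.1 CPM, ahead of pcna1 at 124 ± 9.56 CPM and MCM6 at 124 ± 9.97 CPM. SMC3, a cohesin gene, stood at 108 ± 2.10 CPM and krp4, a kinesin gene, at 223 ± 9.61 CPM. The D-type cyclin gene cycD2 stood at 139 ± 3.28 CPM. The histone and DNA replication medians lay above all 10000 random lists (percentile 100), and those of kinesins, mitosis and cell cycle regulators at percentiles 99.99, 99.48 and 99.13. The random lists drew on 32260 genes with a count, of which 10116 stayed below 1 CPM in every library. Of the 29 lists, 16 lay at percentile 99 or above, so such a percentile is not particular to division. In the chromatin list, dmt101, a DNA methyltransferase gene, led at 117 ± 5.26 CPM.

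Growth lists differed in level, with expansins lowest at percentile 56.31, or 70.53 without members at 0. The 35 cytosolic ribosomal protein genes took 1.08 ± 0.0326% of counts (SD, n = 4), led by rps27 at 1075 ± 53.8 CPM. The 14 translation factor genes took 0.930 ± 0.0123%, with tif5A at 1158 ± 38.6 CPM and elfa2 at 939 ± 25.6 CPM. The 16 tubulin genes took 0.883 ± 0.0265%. All 9 primary wall cellulose synthase genes were detected, led by cesa2 (416 ± 22.0 CPM), CesA-9 (359 ± 16.5 CPM) and cesa8 (263 ± 12.97 CPM). Expansins, which loosen walls during elongation, were uneven: 9 of 16 were detected, expB2 stood at 493 ± 49.7 CPM, and expB8 followed at 67.1 ± 5.70 CPM. The actin-binding gene ADF3 stood at 364 ± 14.5 CPM.

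Most genes of the xylem and secondary wall, photosynthesis and seed storage lists stayed below the detection limit. Of 9 xylem and secondary wall genes, 2 were detected: lac3 at 3.78 ± 0.599 CPM and LAC1 at 2.39 ± 0.465 CPM, both laccase genes. The secondary wall cellulose synthase gene cesa11 stood at 0.393 ± 0.120 CPM. In the photosynthesis list, 2 of 22 were detected, and C4ppdkZm1 carried most of its counts at 388 ± 44.0 CPM. That gene is also listed under a cytosolic form's name. ME1 followed at 14.1 ± 2.14 CPM and CAB1 at 0.567 ± 0.190 CPM. None of 31 seed storage genes was detected in every library, the highest being bz15 at 0.457 ± 0.190 CPM. With members at 0 kept, the medians of these lists lay at percentiles 0.90, 0 and 0 of random lists of genes with a count, and at 1.26, 0.11 and 2.41 over members with a count only. The xylem value was 0.51 without replicate 4 and 1.6 without replicate 2.

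Genes for sucrose cleavage, fermentation and glycolysis were abundant. The low oxygen list of 12 genes, which holds sucrose synthase, pyruvate decarboxylase, alcohol dehydrogenase and haemoglobin genes, took 0.752 ± 0.0524% of counts, with sh1 at 996 ± 75.9 CPM and pdc3 at 945 ± 55.8 CPM after sus1. The glycolysis list of 16 genes took 1.27 ± 0.0339%, with gpc4 at 1515 ± 51.7 CPM. Without an unsubmerged group, these levels can neither show nor exclude a response to water.

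Defence and stress lists differed in level. In the benzoxazinoid list 10 of 14 genes were detected, and glu1 was followed by Bx7 at 905 ± 51.6 CPM and bx9 at 331 ± 19.5 CPM. gst5, a glutathione S-transferase gene, stood at 1443 ± 196 CPM and gst1 at 797 ± 46.1 CPM. HSP90-2 stood at 821 ± 49.7 CPM. The dehydrin and LEA list held RAB15 at 774 ± 32.4 CPM and dhn2 at 596 ± 46.0 CPM, while its median was at percentile 39.39. The peroxidase gene pox1 stood at 87.5 ± 3.39 CPM, against 2.95 ± 0.468 CPM for PER70, and that list's median was at percentile 15.43. The antioxidant gene cat1, for a catalase, stood at 156 ± 12.2 CPM.

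Transport and hormone lists varied in level. Of 30 aquaporin genes 19 were detected, led by PIP2-6 (278 ± 13.5 CPM), TIP1-1 (198 ± 32.0 CPM) and PIP2-1 (195 ± 19.3 CPM), with the list at percentile 73.36, or 95.76 without members at 0. The phloem list was led by Tie-dyed2 at 101.2 ± 4.30 CPM and sut2 at 52.8 ± 2.39 CPM, at percentile 90.32. ARF18 (271 ± 8.33 CPM) and PIN1a (197 ± 8.15 CPM), an auxin efflux carrier gene, led the auxin list, at percentile 81.1, or 96.13 without members at 0. RR9, a cytokinin response regulator gene, stood at 131 ± 2.97 CPM in a list at percentile 38.62, or 47.05 without members at 0. Of 26 stem cell and patterning genes 10 were detected, with rld2 at 46.0 ± 2.65 CPM and SCR, the SCARECROW gene, at 40.3 ± 2.7 CPM, and the list lay at percentile 0.79, or 12.37 without its 9 members at 0. GRF12 led the growth-regulating factor list at 64.3 ± 2.53 CPM. The remaining list medians were at percentile 100 for ribosomal proteins, translation factors, tubulins, cellulose synthases, low oxygen response and glycolysis. They were at 99.96 for chaperones, 99.85 for benzoxazinoids, 99.67 for actins, 99.31 for chromatin, 99.06 for antioxidants, 92.77 for glutathione S-transferases and 93.1 for growth-regulating factors.

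**Figure D1:**
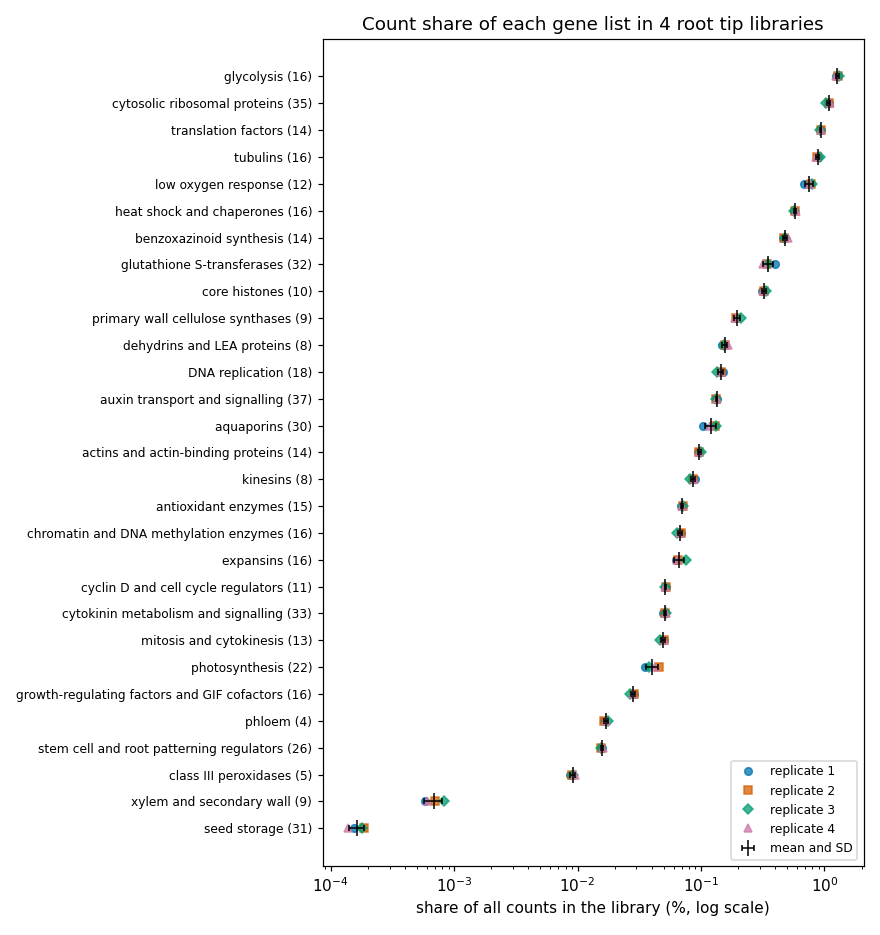
Share of all counts in percent, on a log axis, for each of 29 gene lists (number of genes in parentheses) in the 4 libraries, with the mean and SD. Glycolysis is highest at 1.27% and seed storage lowest at 0.000164%.

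Differences between list medians were taken within each library. The DNA replication median exceeded that of xylem and secondary wall by 6.14 ± 0.05 on the log2(CPM + 1) scale (SD, n = 4), in 4 of 4 libraries. The low oxygen median minus the glycolysis median was -1.15 ± 0.16 (0 of 4 libraries above 0). In the two-sided exact sign-flip permutation test, 2 of 16 sign patterns were as extreme for each, the smallest share that 4 libraries can give, so neither could pass 0.05. The photosynthesis median was 0 CPM in every library, so the planned differences from it, 6.24 ± 0.04 for DNA replication and 7.66 ± 0.03 for ribosomal protein genes, are the medians of those lists alone. Their sign was fixed, and the test on them says nothing. The pseudocount sets the size of all differences from xylem and photosynthesis.

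In 28 of 29 lists the highest member exceeded the second by more than the spread between replicates (limma, adjusted p below 0.05). The leading member was picked on the same values, which favours a positive ratio, and the simulation did not cover that step. The widest gaps were C4ppdkZm1 over ME1 (log2 ratio 4.74, SE 0.13, limma adjusted p = 3.34e-10), pox1 over PER70 (4.68, SE 0.10, limma adjusted p = 1.1e-10) and expB2 over expB8 (2.87, SE 0.05, limma adjusted p = 1.51e-11), each first in 4 of 4 libraries. The exception was seed storage, where bz15 led z1A1_2 by 0.07 (SE 0.09) in 2 of 4 libraries (limma adjusted p = 0.427).

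Replicates differed little for most genes. Pairwise Pearson r of log2(CPM + 1) across genes, which are not independent replicates, was 0.996 to 0.997, and Spearman rho was 0.995 to 0.997. The common biological coefficient of variation was 5.97%. Between any pair, 1638 to 3924 genes passed the chi-square test against Poisson counting error at an adjusted p of 0.05, with reads taken as independent. Over all 4 libraries 5847 of 22752 genes (25.7%) varied beyond counting error. The share was 3.02% of genes below 1 CPM, 11.97% at 1 to 10 CPM, 28.8% at 10 to 100 CPM and 71.0% at 100 CPM or more. The median coefficient of variation ran the other way, at 21.2, 11.5, 5.37 and 3.92%, since low counts carry more counting error. The chi-square test detects a smaller spread at higher counts, so the rise in share does not show that abundant genes vary more. Without replicate 3, 3074 genes varied beyond counting error.

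LOC100192350 and 8 other genes varied more than others of their abundance (edgeR quasi-likelihood dispersions, adjusted p below 0.05). LOC100192350 (asn3) is an asparagine synthetase gene and stood at 1.68, 18.3, 2.05 and 0.812 CPM in replicates 1 to 4 (edgeR adjusted p = 0.000903). LOC100192762 stood at 27.1, 92.6, 40.3 and 28.1 CPM (edgeR adjusted p = 0.000903). LOC541648 (lkrsdh1), a lysine degradation gene, stood at 76.0, 120.3, 66.6 and 44.1 CPM (edgeR adjusted p = 0.00713). Replicate 2 was also highest for LOC100501517 (12.99 CPM), LOC100272715 (44.0 CPM) and LOC100283693 (14.2 CPM). Replicate 4 was highest for LOC100277838 (217.7 CPM) and LOC100280589 (170.0 CPM), and replicate 1 for LOC103626520 (33.1 CPM). The count of 9 was not stable: it was 494 with all genes with a count, 174 as DESeq2 dispersion outliers and 2 with a non-robust prior. It was 2 without replicate 2, 3 without replicate 4 and 100 without replicate 3. None of the 9 belonged to any of the 26 lists with enough tested members, so Fisher's exact test gave 0 lists, with 0 at an unadjusted p below 0.05, and could give nothing else. With all genes with a count, 3 lists passed. A second planned measure, the median log2 ratio of dispersion to trend, ran from -1.22 for translation factors to 2.09 for photosynthesis (3 tested members). It was 1.76 for aquaporins, 1.64 for expansins and 1.625 for low oxygen response, against -0.22 for all tested genes. No test was made on this measure, and genes of a list are not independent.

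**Figure D2:**
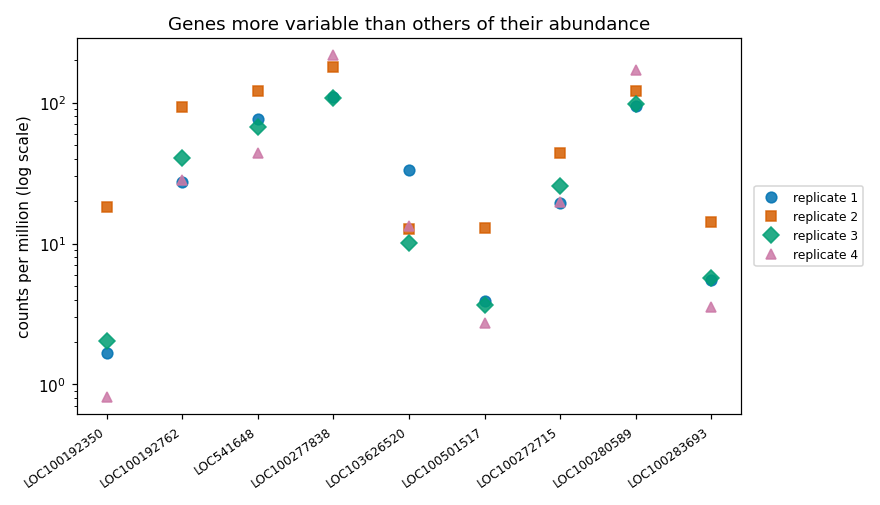
CPM, on a log axis, of the 9 genes more variable than others of their abundance, 1 point per replicate. Replicate 2 is highest for 6 genes, among them LOC100192350 at 18.3 CPM.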

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

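The outlier criterion was set before the data were examined. For replicate 3, the test on tip length was written before its result was seen, and the test on abundant genes was chosen only after the shares were seen. A library stood far from the other 3, by Dixon's criterion, in 13 of 158 values tried. Chance flags about 1 in 20. That rate does not hold for the 9 genes picked for their spread, which gave 3 of the 13. Without them 10 of 149 values stood apart, against 7.45 by chance, and lists and their members are not independent.

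Replicate 3 stood apart in 8 of the 13. Its share of counts was 0.0468% for mitosis and cytokinesis against a mean of 0.0501% in the others (gap to range 0.851) and 0.0641% against 0.0684% for chromatin and DNA methylation enzymes (0.839). Its share was 0.211% against 0.191% for primary wall cellulose synthases (0.922). Among genes it was lower for SMC3 (104.7 against 108.9 CPM, 0.881), CPN60I (251.4 against 300.3 CPM, 0.861), nfd104 (94.1 against 100.1 CPM, 0.834) and met5 (77.7 against 88.2 CPM, 0.899), and higher for sut2 (56.4 against 51.6 CPM, 0.897).

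For the list shares of replicate 3, a total changed by a few abundant genes is argued against, since it would move every list alike. The log2 ratios to the others were -0.10, -0.09 and 0.14 for mitosis, chromatin and cellulose synthases, a range of 0.24. Tips cut slightly longer may account for them only if the added cells elongate more and divide less than the rest. Whether cells just past 1 mm do so was not measured. The test used lists not flagged above, but they come from the same libraries, so it is not independent of the pattern. Over 10 expansins the median log2 ratio of replicate 3 to the others was 0.15, with 5 highest and 1 lowest in replicate 3. Over 36 DNA replication, histone and kinesin genes it was -0.09, with 9 highest and 21 lowest in replicate 3. The difference of 0.24 lay above all random pairs of lists (percentile 100). Random lists hold unrelated genes, whereas members of these lists may move together, so that percentile does not say how often replicates differ this much. Histones went the other way, with a share of 0.336% in replicate 3 against a mean of 0.318% in the others. Tissue makeup was not measured, and the design, with 1 group, gives no difference between conditions to test.

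Replicate 2 was far above the others for LOC100192350 (18.3 against 1.52 CPM, 0.929) and LOC100501517 (12.99 against 3.46 CPM, 0.883). Replicate 1 was far above for LOC103626520 (33.1 against 11.98 CPM, 0.858) and gst5 (1737 against 1346 CPM, 0.916). Replicate 4 was above for LOC103639924 (1840 against 1646 CPM, 0.962).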

How the results depend on the processing

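Leaving replicates out of list levels and of single genes, list levels over members with a count only, and CPM with TMM factors were chosen after seeing the data. Planned settings moved several results, as given below. Beyond the changes given here, no setting moved a value by more than its SD between replicates (for list levels, that of the median), or a count by over 1.5 times.

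Detection gave 22335 genes at 0.5 CPM and 22829 at 10 counts, against 20971. The count of genes more variable than others of their abundance depended most on the setting: it was 9, but 494 with all genes with a count, 2 with a non-robust prior and 174 as DESeq2 dispersion outliers, and 2 to 100 with a replicate left out. The 494 held the 9, and both genes of the non-robust prior were among them. Genes varying beyond counting error numbered 3074 to 5193 with a replicate left out, lowest without replicate 3. The coefficient of variation was then 0.0519 to 0.0629. With all genes with a count, 3 lists passed for variability, against 0. The xylem list lay at percentile 0.51 without replicate 4 and 1.6 without replicate 2, against 0.90, and photosynthesis stayed at 0. The cause of these changes was not tested.

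Over members with a count only, fewer low members enter, and percentiles were 99.87 for actins, 70.53 for expansins, 1.26 for xylem, 95.76 for aquaporins, 100 for chaperones, 20.21 for peroxidases, 99.93 for benzoxazinoids, 96.13 for auxin, 47.05 for cytokinin, 12.37 for patterning, 0.11 for photosynthesis and 2.41 for seed storage.

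With a pseudocount of 0.1, DNA replication exceeded xylem by 8.79 and photosynthesis by 9.54, and ribosomal proteins exceeded photosynthesis by 10.98, since the xylem median is near 0 CPM and the photosynthesis median is 0. With detected members only, low oxygen minus glycolysis was -0.87, and the other differences had too few members for a value.

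Without the 25 most abundant genes, lists that lost members fell in share of counts: tubulins to 0.381%, glycolysis 0.696%, low oxygen response 0.398%, chaperones 0.215%, glutathione S-transferases 0.219%, benzoxazinoids 0.170% and translation factors 0.815%. The others rose because the total shrank: histones to 0.342%, DNA replication 0.153%, mitosis 0.0522%, kinesins 0.0913%, cell cycle regulators 0.0546%, ribosomal proteins 1.15%, actins 0.103%, cellulose synthases 0.208%, phloem 0.0179%, peroxidases 0.00966%, antioxidants 0.0744%, dehydrins 0.165%, auxin 0.142%, cytokinin 0.0540%, patterning 0.0167%, growth-regulating factors 0.0297% and chromatin 0.0714%. Alternatives on TPM were not run, for lack of exon lengths.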

Other observations

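The tests on green or seed tissue, sugar starvation and wounding were written before their results were seen, but after replicate 2 had been noticed and after asn3 and lkrsdh1 had been seen. The low oxygen test was written after adh2 had been seen, and its demand that replicate 2 exceed each other library was added after its first result was seen. pr5 was left out of the wounding genes because its values had been seen.

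Replicate 2 was the highest library for 6 of the 9 genes more variable than others of their abundance. Over the 118 genes with an unadjusted p below 0.001 it was highest for 56, and replicate 3 for 42. Material of green or seed tissue stays open. The photosynthesis and seed storage lists together took 1.17 times the share in replicate 2 that they took in the others. The test counted a ratio of 1.2 or lower against this cause and set a higher bound for it, which was not reached. The ratio of 1.17 was too close to 1.2 for the spread of those libraries. C4ppdkZm1 alone held 95.7% of the share of both lists, and the ratio was 1.21 without it, also short of the higher bound. The design, with 1 group, gives no difference between conditions to test.

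Hypotheses on the seedlings of replicate 2 were tried on gene lists, with genes chosen for the test and not by the naming rule. Low oxygen may have differed: 11 measured genes had a median log2 ratio of 0.15 to the mean of the others, at percentile 100 of random lists of like abundance. Those random lists hold unrelated genes, whereas low oxygen genes may move together. The percentiles therefore do not say how often replicates differ this much. The ratio was 0.21 against replicate 1 alone, which was lowest for 8 of the 11, and 0.15 against replicate 4 (percentile 99.99), but 0.02 against replicate 3 (percentile 77.85), so replicate 2 was not set apart from every other library. The 11 include adh2, which prompted the test. Without it, a check added after that result was seen, the median was 0.13 (percentile 100), and 0.02 against replicate 3 (percentile 79). Sugar starvation, with 9 measured genes such as asn1 and gdh1, gave a median of 0.04 at percentile 90.6. Wounding, with 7 measured genes such as MPI and aos1, gave 0.004 at percentile 64.7. Both medians were positive, but neither percentile reached the bound set for its test, so neither is settled. Members of both lists went both ways. Against replicate 3 alone the median was -0.03 for sugar starvation (percentile 22.24) and -0.02 for wounding (percentile 51.78).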
